A study of Mus musculus with 17 samples.

How the data were processed

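Gene expression was measured in mouse macrophages grown from bone marrow. Per the labels, irradiated mice had been reconstituted with fetal liver cells of SOCS3+/+ or SOCS3-/- embryos, and macrophages were differentiated from donor-derived cells of their marrow. They are called WT and KO here. SOCS3, the suppressor of cytokine signalling 3, is a feedback inhibitor of the receptor subunit gp130 that IL-6 signals through. Cells were left unstimulated or were stimulated with IL-6 at 10 ng/ml for 100 or 400 min, and total RNA was taken. The 17 arrays fall into 6 groups: 2 arrays of unstimulated WT cells and 3 arrays of each of the other 5 groups, and each array was assigned by its label. The labels number the replicates 1 to 3 but do not say whether they are separate cultures, mice or donors. The p-values then measure only the spread between these samples, which may be technical.

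The deposited table gives 1 positive linear intensity per probe set and array for 12488 probe sets, with names of the kind used on Affymetrix arrays. The intensity ranged from 0.3 to 91970.4. From the values, the mean intensity after leaving out the lowest and highest 2% of probe sets was about 500 on all 17 arrays, so the deposited values had been scaled per array. The software, the background correction and the scaling procedure are not given in the sources used here. The table has no detection calls, so signal over background could not be read probe set by probe set. The number of arrays limits the precision.

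The platform's annotation gave 1 gene symbol to 10855 probe sets and several genes to 396, and left 1237 not named. Updating through the gene ID changed 0 symbols. Probe sets with several genes or none are called unnamed. Names of the neighbours of Socs3 were looked up in a table of RefSeq genes of assembly GRCm38.p6; no coordinates are given, since the files name no genome build.

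The rule for normalization, the filter, the tests, the gene lists and the choice of named genes were fixed before the data were examined. The array medians of the deposited values differed by 0.4 on the log2 scale, above the limit of 0.3 set in advance, so the values were quantile normalized between arrays. They were then set to a floor at the 10th percentile of all values, an intensity of 22.01, and log2 transformed. Between a pair of groups, the fold change of a gene with values at the floor understates the difference. A difference between the KO and WT responses can then be too small or too large. The 66 array control probe sets were left out of the tests. A probe set was tested when it lay above its array's 40th percentile on at least 2 arrays, a filter blind to the groups; 9871 probe sets passed, of which 8730 had 1 symbol, for 7063 genes. Levels in the text are group means ± SD of the normalized intensity before the floor was set.

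The test was limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group over all 17 arrays, so that the 6 groups share one estimate of the spread, and the two-sided moderated test of eBayes (prior degrees of freedom 2.6, residual degrees of freedom 11). The p-values were adjusted by Benjamini-Hochberg over the probe sets tested in each of 9 comparisons, and a probe set was called at an adjusted p under 0.05. The comparisons were each time against unstimulated cells in WT and in KO, KO against WT at each time, and the difference between the KO and WT responses at each time. Fold changes are log2 values, with their standard errors (SE) in parentheses where given.

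Gene groups were 22 lists fixed before the data were examined. The results of 1 of them are not reported here; it remains in the number of list tests. The others cover genes stimulated by type I interferon, MHC class I and class II presentation, targets of STAT3, IL-6 and IL-10, parts of JAK-STAT and gp130 signalling, NF-kappaB inflammatory genes, immediate early genes, acute phase and complement genes, alternative activation, the cell cycle, lysosome and phagocytosis, and macrophage markers. Markers of other cells formed 7 lists: neutrophils and myeloid precursors, B cells, T and NK cells, erythroid cells and megakaryocytes, mast cells and basophils, fibroblasts and stroma, and dendritic cells and osteoclasts. The last lists hold sex-linked genes and the chromosome 11 neighbours of Socs3. Each gene entered with the probe set of the highest mean. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 189 list tests, and again with an estimated correlation. Of the 43 list calls, 17 held with the estimated correlation and 26 did not. In all of the 43, the median, the mean and the test had the same sign. Lists with under 5 tested genes had no list test. Lists share members: 19 of the 40 tested genes of the STAT3 list are also on another list.

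Named genes were chosen by rule: in each comparison the 10 called genes with the largest rise and the 10 with the largest fall, in each list up to 4 called members with the largest change or, with none called, the 2 members of smallest p, and always Socs3, Socs1, Stat3, Irf1, Irf7, Il6ra, Il6st, Cxcl10 and Bcl3. A gene named outside the rule is said to be so. Of several called probe sets of a gene, the one with the largest change is named.

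The procedure was tested on simulated data made from the real means and spread, for the KO 400 min comparison over 9871 probe sets. Of 50 probe sets changed by each fold, 10% were recovered at 2-fold, 44% at 4-fold, 92% at 8-fold and 96% at 16-fold, and 5 of 126 calls were false. Over 7063 genes, a list of 40 genes shifted by 0.5 had an adjusted p of 5e-05, and 0 of 20 unshifted lists were called. The simulated genes varied independently of each other, and no replicate 3 difference was built in. The simulation therefore cannot show how often lists of correlated genes are called falsely.

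The alternatives tried were no filter, a stricter filter, the values as deposited, a floor at the 2nd percentile, the replicate number as a block, a fit of only the groups compared, a trended and robust eBayes, array weights, the mean over the probe sets of a gene, an estimated correlation, and leaving out each array in turn. Those added after the data were seen were the arrays of replicate 3 as a batch block, a fit within the arrays of replicates 1 and 2 only, and a floor at the 40th percentile. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Scanner files are not analysed here.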

Results

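Expression was compared on 17 arrays of bone marrow-derived macrophages: WT cells unstimulated (n = 2) and after 100 and 400 min of IL-6 (n = 3 each), and KO cells unstimulated and after 100 and 400 min of IL-6 (n = 3 each). The question is what the loss of SOCS3 changes in the genes that IL-6 turns on or off. The median deposited intensity of an array lay between 164.25 and 216.95. Correlations between arrays over the tested probe sets, on the normalized log2 values, were 0.855 to 0.917 within groups, with a median of 0.875, against a median of 0.870 between groups.

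Socs3 was read by a pair of probe sets, called first and second here. In WT cells the deposited intensity of Socs3 on the first was 110.7 and 72.9 on the unstimulated arrays. It was 2647.6, 1911.0 and 429.5 at 100 min and 2441.2, 2003.8 and 2104.4 at 400 min, for replicates 1 to 3. In KO cells Socs3 lay at 17.3, 28.8 and 14.9 unstimulated and at 78.3, 77.6 and 160.2 at 100 min. At 400 min it lay at 45.2 and 77.4 on the KO arrays of replicates 1 and 2 and at 883.7 on the array labelled KO 400 min replicate 3. Socs3 on the second probe set read 110.7, 78.2 and 784.3 on those KO arrays and 1333.0, 1089.7 and 1301.6 on the WT arrays at 400 min. On 8 of the 9 KO arrays Socs3 on the first probe set was below each stimulated WT array, and the array labelled KO 400 min replicate 3 was above WT 100 min replicate 3. The labels do not say which part of the gene was deleted, so it is not known whether the probe sets lie in it. Directions drawn from the KO 400 min group rest in part on that array, and counts without it are given below.

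The arrays of the genotypes were also separated by the sex-linked genes Eif2s3y and Xist. Eif2s3y, a gene of the Y chromosome, lay between 245 and 790 on the 8 WT arrays and between 7.67 and 112 on the 9 KO arrays. Xist, the RNA of the inactive X chromosome, lay between 11.1 and 188 on the WT arrays and between 228 and 993 on the KO arrays. The other Y-linked genes read, Kdm5d and Uty, were too dim to be tested. Kdm5d did not separate the genotypes, with means of 33.0, 19.3 and 64.6 in WT cells unstimulated and at 100 and 400 min and 82.2, 18.3 and 61.3 in KO cells. Uty had means of 22.80, 90.11 and 72.06 in WT and 24.52, 16.98 and 12.56 in KO cells, so that it was no lower in unstimulated KO cells. Neither Eif2s3y nor Xist passed limma's test over all probe sets: Eif2s3y was -3.46 (SE 0.69, adjusted p = 0.0529) and Xist 2.84 (SE 0.66, adjusted p = 0.102) in KO against WT at 400 min. Adjusted over the list alone, 2 of the 4 tested sex-linked genes were higher and 1 was lower in that comparison. At 100 min these counts were 2 and 1, and unstimulated 3 and 1. Every comparison of KO with WT is therefore also one between arrays with different levels of Eif2s3y and Xist.

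Of the 5 arrays of replicate 3, 4 stood apart along the first principal component, which held 12.7% of the variance: they lay at 58.08, 45.21, 30.49 and 26.61, and the highest of the 12 arrays of replicates 1 and 2 at 2.27. The array labelled KO 400 min replicate 3 lay at 0.89, within the range of those 12. Genes of the cell cycle list were higher on the 5 arrays, with a median of 0.75 (adjusted p = 9.25e-22, and adjusted p = 0.00448 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was 2.64 (SE 0.16) higher. The median was lower for the type I interferon list, at -0.64 (adjusted p = 1.32e-06; adjusted p = 0.172 with an estimated correlation). The lysosome list was at -0.32 (adjusted p = 0.00165), the macrophage list at -0.26 (adjusted p = 0.0411) and the neutrophil and myeloid precursor list at -0.5 (adjusted p = 0.00548); with an estimated correlation their adjusted p was 0.172, 0.177 and 0.0983. Unstimulated WT cells have no replicate 3 array, so comparisons with that group set a group without such an array against groups with 1 of 3. Values with replicate 3 as a batch block and within replicates 1 and 2 therefore stand beside the counts.

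**Figure D1:**
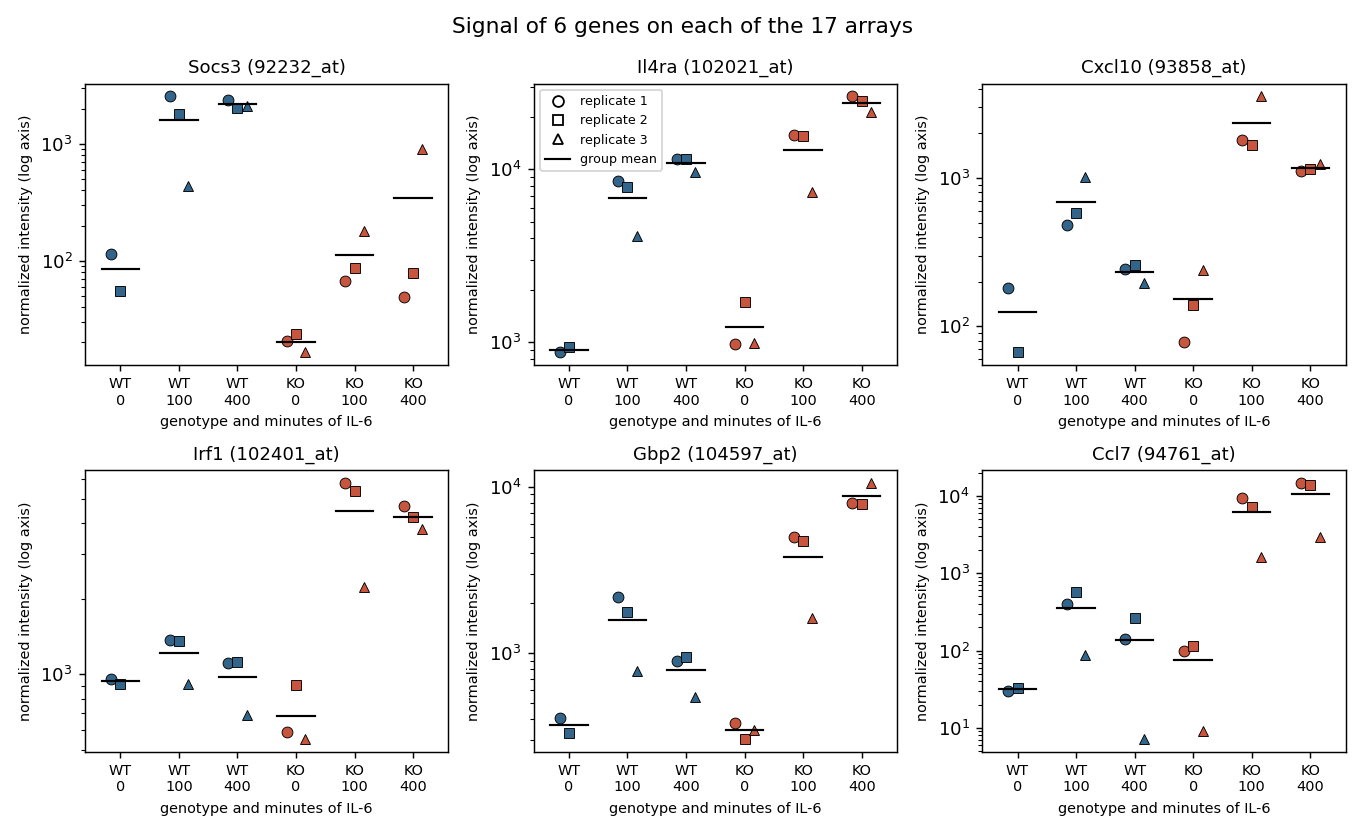
Normalized intensity (log axis) of Socs3, Il4ra, Cxcl10, Irf1, Gbp2 and Ccl7 on each of the 17 arrays, by group; marker shapes give the replicate number, blue is WT, red is KO and black bars are group means. The array labelled KO 400 min replicate 3 reads 903 for Socs3, and Il4ra has means of 24330 in KO and 10870 in WT cells at 400 min.

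In WT macrophages IL-6 raised Il4ra, a receptor chain for IL-4 and IL-13, from 909 ± 41.1 (SD, n = 2) to 6873 ± 2406 (SD, n = 3) at 100 min and 10870 ± 1096 (SD, n = 3) at 400 min. It was the only probe set called in WT cells at either time: 2.85 (SE 0.39, adjusted p = 0.0456) at 100 min and 3.58 (SE 0.39, adjusted p = 0.00339) at 400 min, higher on all of the stimulated WT arrays than on both unstimulated ones. Other genes had large values that did not pass. At 100 min these were Iigp1, an interferon-inducible GTPase (4.45, adjusted p = 0.0684), Casp4, an inflammatory caspase (3.76, adjusted p = 0.0684), Socs3 (3.99 on the first probe set, adjusted p = 0.395; 2.91 on the second, adjusted p = 0.593) and the chemokine gene Cxcl10 (2.58, adjusted p = 0.316). At 400 min Fcgr2b, an inhibitory Fc receptor, was at 3.67 (adjusted p = 0.0734) and Socs3 at 4.78 (first probe set, adjusted p = 0.222).

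As a group, the targets of STAT3, IL-6 and IL-10 were higher in WT cells. Of 40 tested genes 1 rose at each time; adjusted over the list alone 5 rose at 100 min and 7 at 400 min. The medians were 0.40 (adjusted p = 0.0011, and adjusted p = 0.0141 with an estimated correlation) and 0.38 (adjusted p = 2.96e-05, and adjusted p = 0.00642 with an estimated correlation). Genes of the type I interferon list had a median of 0.22 at 100 min (adjusted p = 0.027; adjusted p = 0.754 with an estimated correlation) and at -0.53 at 400 min (adjusted p = 0.0107; adjusted p = 0.722 with an estimated correlation). None of its 38 genes was called in WT cells; adjusted over the list alone 1 was higher at 100 min and 0 at 400 min. JAK-STAT and gp130 parts were at 0.06 at 400 min (adjusted p = 0.000848; adjusted p = 0.0591 with an estimated correlation), with 1 of 35 risen and 7 adjusted over the list alone. Fibroblast and stroma markers were at -0.31 at 400 min (adjusted p = 0.0379; adjusted p = 0.217 with an estimated correlation), with 0 of 15 called and 0 adjusted over the list alone. These type I interferon genes and the cell cycle list also differed between replicate 3 and the other arrays.

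Unadjusted, 604 probe sets at 100 min and 618 at 400 min had p under 0.05 in limma's test, where 494 of 9871 would by chance. The WT counts moved with single arrays and with replicate 3: with replicate 3 as a batch block 3 probe sets were called at each time, and within replicates 1 and 2 the counts were 22 (22 higher) at 100 min and 16 (11 higher, 5 lower) at 400 min. Without WT unstimulated replicate 1 they were 20 and 16. Without WT unstimulated replicate 2 both were 0. At 100 min the count was also 0 without replicate 1 or 2 of WT 100 min, KO 100 min or KO 400 min, without replicate 1 or 3 of KO unstimulated, and without WT 400 min replicate 3 or the array labelled KO 400 min replicate 3; it was 3 without WT 400 min replicate 1, 5 without KO unstimulated replicate 2 and 4 without WT 100 min replicate 3. At 400 min it was 2 without WT 100 min replicate 1 or KO unstimulated replicate 3, 4 without WT 400 min replicate 1, and 5 without KO unstimulated replicate 2 or the array labelled KO 400 min replicate 3. Il4ra at 100 min lost its call in 13 of 17 such fits, all except those without WT 400 min replicate 1, KO unstimulated replicate 2, WT 100 min replicate 3 or KO 100 min replicate 3 (highest adjusted p = 0.3), and at 400 min without WT unstimulated replicate 2 (adjusted p = 0.0958). The type I interferon list lost its call at 100 min without replicate 1 or 2 of WT unstimulated or WT 100 min (highest adjusted p = 0.463) and at 400 min without WT unstimulated replicate 1 or WT 400 min replicate 3 (highest adjusted p = 0.332). The fibroblast list lost its call at 400 min without WT unstimulated replicate 2 or WT 400 min replicate 2 or 3 (highest adjusted p = 0.457).

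In KO macrophages IL-6 raised the chemokine genes Ccl7, Ccl12, Ccl2, Ccl4 and Cxcl10 within 100 min. Ccl7, a monocyte chemoattractant, went from 75.0 ± 57.5 (SD, n = 3) to 6090 ± 4030 (SD, n = 3). The related chemokine genes Ccl12 and Ccl2 rose by 4.76 (SE 0.69) and 4.74 (SE 0.90). Cxcl10, which encodes a chemokine for activated T cells, rose from 152 ± 80.5 to 2339 ± 1041 (SD, n = 3 each; adjusted p = 0.00169), and Irf1, an interferon regulatory factor, by 2.63 (SE 0.36, adjusted p = 0.00326). Ch25h, cholesterol 25-hydroxylase, rose by 4.13 (SE 0.43, adjusted p = 0.00105) and Il4ra by 3.37 (SE 0.35, adjusted p = 0.00105). Selp, the adhesion molecule P-selectin, rose by 4.24 (SE 0.56, adjusted p = 0.00299). In all, 53 probe sets rose and 4 fell. Those that fell included the transcription factor genes Foxd1 (-2.08, SE 0.37), Tgif1 (-1.77, SE 0.30) and Cebpa (-1.27, SE 0.24), the last a regulator of myeloid differentiation. Foxd1 lay at or under the floor on 2 of the 3 KO arrays at 100 min.

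Among interferon-inducible genes, Iigp1 rose by 4.28 (SE 0.60), and the guanylate-binding protein genes Gbp2 by 3.31 (SE 0.44) and Gbp7 by 3.27 (SE 0.48). Of the type I interferon list 2 of 38 genes rose, Cxcl10 and Plscr1 (1.95), and 11 adjusted over the list alone; its median was 0.86 (adjusted p = 5.85e-16; adjusted p = 0.0969 with an estimated correlation). That list is lower on replicate 3 arrays, of which each KO group holds 1. Of the STAT3 list 7 of 40 rose, among them Il4ra, Gadd45g (3.23), Fcgr2b (3.09) and Zfp36 (2.03), a factor that destabilises cytokine mRNAs; adjusted over the list alone 12 rose and 2 fell. Its median was 0.57 (adjusted p = 3.28e-11, and adjusted p = 0.000437 with an estimated correlation). Of the NF-kappaB list 4 of 38 rose, Ccl7, Ccl12, Ccl2 and Ccl4 (2.64), and 7 adjusted over the list alone, with a median of 0.48 (adjusted p = 4.69e-06, and adjusted p = 0.00617 with an estimated correlation). JAK-STAT and gp130 parts had a median of 0.18 (adjusted p = 0.0389; adjusted p = 0.217 with an estimated correlation), with 2 of 35 risen, Il4ra and Il13ra1 (2.31), and 5 adjusted over the list alone. Of 28 immediate early genes 2 rose, Myc (2.28) and Zfp36, and the list was not called (adjusted p = 0.0834). Myc was at or under the floor on 2 of the 3 unstimulated KO arrays and on both unstimulated WT arrays.

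Socs1, a relative of Socs3, was at 1.49 (adjusted p = 0.362), Stat3 at 0.80 (adjusted p = 0.365), Bcl3 at 1.97 (adjusted p = 0.0696), Il6st, which encodes gp130, at 0.66 (adjusted p = 0.981), Irf7 at 0.28 (adjusted p = 1) and Il6ra, the IL-6 receptor chain, at -0.41 (adjusted p = 1). Socs3 was at 2.17 (first probe set, adjusted p = 0.672). All 57 calls had the same direction within replicate 3, and 56 of 56 that could be read within replicates 1 and 2. Here and below, such a direction is the sign of the change and not a call. The calls were made with these same arrays, so such agreement was favoured by the choice and is not separate support. A fit of only the groups compared called fewer than the 57, as counted further below. With replicate 3 as a batch block 94 were called and within replicates 1 and 2 125. The count was 24 and 27 without KO 100 min replicate 1 and 2, and 31, 34 and 35 without KO unstimulated replicate 1, 2 and 3. Calls of Ccl12, Iigp1, Selp, Ch25h, Cxcl10, Il4ra, Gbp2, Gbp7, Gadd45g, Ccl4 and Irf1 were kept with each of the 17 arrays left out. The other 11 named genes each lost theirs without 1 or more of the KO unstimulated and KO 100 min arrays, Myc also without either WT unstimulated array or KO 400 min replicate 2 or 3, and Cebpa also without KO 400 min replicate 1. Their highest adjusted p-values were 0.0899 for Ccl7, 0.177 for Ccl2, 0.0711 for Fcgr2b, 0.138 for Il13ra1, 0.178 for Myc, 0.0806 for Zfp36, 0.116 for Plscr1, 0.0942 for Tap1, 0.123 for Foxd1, 0.0768 for Tgif1 and 0.183 for Cebpa. The JAK-STAT list lost its call without replicate 1 or 2 of WT unstimulated, KO 100 min replicate 2 or 3, WT 400 min replicate 3 or KO unstimulated replicate 3 (highest adjusted p = 0.163).

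After 400 min of IL-6, 118 probe sets were higher and 62 lower in KO macrophages than in unstimulated KO cells. A direct comparison of 400 with 100 min in KO cells called 0 probe sets (limma; 891 had an unadjusted p under 0.05), so a larger response at 400 min was not shown. Ccl7 reached 10410 ± 6495 (SD, n = 3). Gbp2 went from 342 ± 36.8 to 8812 ± 1482 (SD, n = 3 each), and Il4ra from 1228 ± 421 to 24330 ± 2521 (SD, n = 3 each; 4.36, SE 0.35, adjusted p = 6.59e-05). Fcgr2b rose by 4.92 (SE 0.51, adjusted p = 0.000277) and Fgl2, a fibrinogen-like protein of macrophages and T cells, by 4.77 (SE 0.74, adjusted p = 0.00542). Arg1, the enzyme that splits arginine into ornithine and urea, rose by 4.59 (SE 0.83, adjusted p = 0.0127), and Ccl8, another monocyte chemoattractant, by 4.41 (SE 0.81, adjusted p = 0.0128). Within replicate 3 alone Arg1 rose by 1.46, and it differed by 0.04 between KO and WT cells at 400 min. Pdcd4, an inhibitor of translation, fell by 3.60 (SE 0.74, adjusted p = 0.0247), Hmga2, a chromatin protein, by 2.33 (SE 0.40, adjusted p = 0.00844) and Srsf10, a splicing factor, by 2.58 (SE 0.44, adjusted p = 0.00951). Other named falls were Nbeal2 (-2.84), Slc46a1 (-2.81), Hspa1b (-2.64), Cd34 (-2.43), Rgs2 (-2.35), Plpp1 (-2.35) and Surf6 (-2.28). Srsf10 and Plpp1 each had a second probe set that was not called (-0.67 and 0.33). Several of these falls ended in the dim range. At 400 min Pdcd4 and Plpp1 lay at or under the floor on 2 of the 3 KO arrays. Slc46a1, Srsf10 and Surf6 did so on 1. Pdcd4 was at 100 ± 147 (SD, n = 3) there and fell by 1.51 within replicate 3.

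Among interferon-inducible genes, Iigp1 rose by 5.16 (SE 0.60), Gbp3 by 3.69 (SE 0.46) and Irf1 by 2.67 (SE 0.36). Of the type I interferon list 5 of 38 rose, among them Isg15 (1.92) and Trim30a (1.58), and 8 adjusted over the list alone, with a median of 0.58 (adjusted p = 2.1e-07; adjusted p = 0.287 with an estimated correlation). Of the STAT3 list 10 of 40 rose and 1 fell; adjusted over the list alone 18 rose and 3 fell. Stat3 itself rose by 1.37 (SE 0.25, adjusted p = 0.0127) and the immediate early gene Fos fell by 2.10 (SE 0.46, adjusted p = 0.0357). The median was 0.73 (adjusted p = 4.37e-11, and adjusted p = 0.000437 with an estimated correlation). Of 38 NF-kappaB genes 5 rose, among them Il1b (2.81), and adjusted over the list alone 5 rose and 1 fell; the median was 0.38 (adjusted p = 0.000821, and adjusted p = 0.0135 with an estimated correlation). JAK-STAT and gp130 parts were at 0.18 with 5 of 35 risen, among them the receptor genes Il13ra1 (3.22) and Csf2rb (3.20) and the phosphatase gene Ptpn1 (1.58), and 7 adjusted over the list alone (adjusted p = 0.000737; adjusted p = 0.0573 with an estimated correlation).

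Of 16 MHC class I genes 3 rose, the peptide transporter gene Tap1 (1.34) and the immunoproteasome genes Psmb10 (1.89) and Psmb9 (1.01); adjusted over the list alone 4 rose and 1 fell (median 0.31, adjusted p = 0.00182; adjusted p = 0.149 with an estimated correlation). Of 15 alternative activation genes 2 rose, Arg1 and Il4ra, and 1 fell, the growth factor gene Igf1 (-1.43; its second probe set -0.02 was not called); adjusted over the list alone 3 rose and 1 fell (median 0.55, adjusted p = 0.0109; adjusted p = 0.0683 with an estimated correlation). Cell cycle genes were lower: 42 of 45 had negative values, 1 was called, the mitotic kinesin gene Kif23 (-1.56), and adjusted over the list alone 3 fell (median -0.67, adjusted p = 2.74e-07; adjusted p = 0.529 with an estimated correlation). The cell cycle list was also higher on replicate 3 arrays than on the other arrays. Of 28 immediate early genes 4 rose, among them Ier3 (2.39), Myc (2.31) and Zfp36 (1.94), and Fos fell; the list was not called. Of the lysosome list 3 of 27 rose, Fcgr2b, Fcgr1 (1.96) and Ctsc (1.04), and of the macrophage markers 1 of 22, Fcgr1. Cd34, a marker on the neutrophil and myeloid precursor list, was the only called member of a list of other cells.

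All 180 calls at 400 min had the same direction within replicate 3, and 178 of 178 that could be read within replicates 1 and 2. These arrays had made the calls, so the agreement is not separate support. A fit of only the groups compared called fewer than the 180, as counted further below. With replicate 3 as a batch block 332 were called and within replicates 1 and 2 309. Without the array labelled KO 400 min replicate 3 the count was 172 (101 higher and 71 lower); it was 75 and 73 without KO 400 min replicate 1 and 2, and 88, 83 and 99 without KO unstimulated replicate 1, 2 and 3. Calls of Ccl7, Ccl12, Iigp1, Fcgr2b, Fgl2, Gbp2, Il4ra, Gbp3, Il13ra1, Cxcl10, Gadd45g, Irf1, Ier3, Zfp36, Tap1, Hmga2 and Srsf10 were kept with each of the 17 arrays left out. The other named genes each lost theirs without 1 or more of the KO unstimulated and KO 400 min arrays, and Il1b, Trim30a, Ctsc, Kif23, Fos, Nbeal2, Hspa1b, Cd34, Rgs2 and Plpp1 also without arrays of other groups; each of the 17 arrays removed the call of 1 or more of these genes when left out. Csf2rb, Psmb9, Il1b, Cd34, Rgs2 and Plpp1 lost theirs without the array labelled KO 400 min replicate 3. Highest adjusted p-values were 0.068 for Arg1, 0.0648 for Stat3, 0.113 for Pdcd4, 0.0928 for Slc46a1, 0.0852 for Isg15, 0.0894 for Psmb10, 0.0823 for Myc, 0.135 for Il1b, 0.159 for Trim30a, 0.117 for Csf2rb, 0.0901 for Ptpn1 and 0.116 for Psmb9. They were 0.0674 for Fcgr1, 0.143 for Ctsc, 0.0681 for Igf1, 0.153 for Kif23, 0.134 for Fos, 0.154 for Nbeal2, 0.159 for Hspa1b, 0.167 for Cd34, 0.16 for Rgs2, 0.148 for Plpp1, 0.0705 for Surf6, 0.082 for Ccl2, 0.0538 for Ccl8 and 0.0773 for Plscr1. The alternative activation list lost its call without KO 400 min replicate 2 (adjusted p = 0.0545).

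Unstimulated KO and WT macrophages were compared as the background of the stimulated comparisons. No probe set was called (limma, smallest adjusted p = 0.0718), and 591 had an unadjusted p under 0.05. The smallest adjusted p was that of an unnamed probe set lower in KO cells (-2.59, SE 0.37), described after its values were seen. Large values that did not pass included higher Casp4 in KO cells (2.91, SE 0.59, adjusted p = 0.354) and lower Eif2s3y (-3.84, SE 0.77, adjusted p = 0.354). Ifi202b, an interferon-inducible gene, was at 2.70 (adjusted p = 0.629) and the apolipoprotein gene Apoe at -3.70 (adjusted p = 0.834). Irf1 was at -0.50 (adjusted p = 0.908) and Socs3 at -1.82 (first probe set, adjusted p = 0.862).

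Of the 21 lists tested, that of the cell cycle alone was called between unstimulated cells. Of its 45 genes 39 were higher in KO, with 0 called and 0 adjusted over the list alone (median 0.36, adjusted p = 0.00429; adjusted p = 0.788 with an estimated correlation). This list is higher on replicate 3 arrays, of which the unstimulated KO group has 1 and the WT group none; with replicate 3 as a batch block its median was 0.09 (adjusted p = 0.411) and within replicates 1 and 2 0.002 (adjusted p = 0.906). The call was lost without WT unstimulated replicate 1 or KO unstimulated replicate 3 (highest adjusted p = 0.975). With replicate 3 as a batch block 0 probe sets were called, and within replicates 1 and 2 9. Other limma settings gave 0 with a trended and robust fit and 0 with array weights. The count was 17 without WT unstimulated replicate 1 and 3 without WT 100 min replicate 3.

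At 100 min of IL-6, KO macrophages had more mRNA of the chemokine Ccl4 than WT cells, 1943 ± 163 against 356 ± 116 (SD, n = 3 each; 2.50, SE 0.32, adjusted p = 0.0109). Rabgap1l, which encodes a protein with a Rab GTPase-activating domain, was higher by 2.31 (SE 0.35, adjusted p = 0.0362). Its means were already 146 in KO and 41.7 in WT cells unstimulated, against 149 and 29.55 at 100 min. At 400 min the order was reversed, with 44.9 in KO and 141 in WT cells, and not called. Cd247, the zeta chain of the T cell receptor complex, was at least 2.75 (SE 0.40, adjusted p = 0.0268) higher, at 159 ± 78.9 (SD, n = 3) against the floor on all 3 WT arrays. Its second probe set was at 0.19. At 400 min Cd247 on the named probe set was lower in KO cells, at 45.1 against 134 in WT cells, and not called. A probe set without a gene name, described here after its values were seen, was lower in KO than in WT cells, whose level was 404 ± 94.6 (SD, n = 3) (-3.90, SE 0.33, adjusted p = 0.000156). It is the unnamed probe set that had the smallest adjusted p between unstimulated cells, where it was at -2.59. Eif2s3y separates the same arrays, so whether this difference goes with SOCS3 or with the sex of the cells cannot be told apart. Socs1 was at 2.43 (adjusted p = 0.0935), Irf1 at 1.78 (adjusted p = 0.127), Cxcl10 at 1.74 (adjusted p = 0.409) and Socs3 at -3.64 (first probe set, adjusted p = 0.368), none of them called. In this comparison 483 probe sets had an unadjusted p under 0.05 in limma's test, where 494 would by chance.

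Of the NF-kappaB list 1 of 38 genes was called at 100 min, Ccl4, and 5 were higher adjusted over the list alone (median 0.26, adjusted p = 9.35e-05, and adjusted p = 0.00829 with an estimated correlation). The STAT3 list was higher in KO cells with 0 of 40 called and 1 adjusted over the list alone (median 0.31, adjusted p = 0.000369, and adjusted p = 0.0103 with an estimated correlation). For the type I interferon list the median was 0.34 with 0 of 38 called and 3 adjusted over the list alone (adjusted p = 5.09e-05; adjusted p = 0.467 with an estimated correlation). JAK-STAT and gp130 parts were at 0.15 with 0 of 35 called and 1 adjusted over the list alone (adjusted p = 0.0102; adjusted p = 0.136 with an estimated correlation). Mast cell and basophil markers were at -0.57 with 0 of 5 called (adjusted p = 0.0383; adjusted p = 0.147 with an estimated correlation).

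The 4 calls at 100 min had the same direction within replicate 3 and within replicates 1 and 2. These are signs only, so they do not show that each was also called within replicates 1 and 2. They were read on arrays that had helped to make the calls. A fit of only the groups compared called fewer than the 4, as counted further below. With replicate 3 as a batch block 16 probe sets were called, and within replicates 1 and 2 40, among them Socs3 (-4.82, SE 0.39, adjusted p = 0.0059). The count was 1 without KO 100 min replicate 1 or 2, 2 without replicate 1 or 2 of WT 100 min or WT 400 min, 7 without KO 400 min replicate 1 or WT 100 min replicate 3, and 12 without the array labelled KO 400 min replicate 3. Ccl4 lost its call without WT 100 min replicate 1 or KO 100 min replicate 1 or 2 (highest adjusted p = 0.0692). Cd247 lost it without any of the WT 100 min or KO 100 min arrays or WT 400 min replicate 1 or 2 (highest adjusted p = 0.0923), and Rabgap1l without any of these or of 3 others, KO unstimulated replicate 1 or 2 or WT 400 min replicate 3 (highest adjusted p = 0.14). The type I interferon and JAK-STAT lists lost their calls without WT 100 min replicate 3 (adjusted p = 0.42 and 0.0762), and the mast cell list in 11 of the 17 fits, all except those without WT unstimulated replicate 2, WT 400 min replicate 2, KO unstimulated replicate 3, KO 100 min replicate 1 or KO 400 min replicate 1 or 2 (highest adjusted p = 0.24).

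At 400 min of IL-6, the chemokine genes Ccl7, Ccl2, Ccl12, Ccl4 and Cxcl10 were higher in KO than in WT macrophages. Ccl7 was at 10410 ± 6495 against 137 ± 128 (SD, n = 3 each; 6.48, SE 1.05, adjusted p = 0.0181). Iigp1 was higher by 4.98 (SE 0.60, adjusted p = 0.00521), Gbp2 by 3.50 (SE 0.44, adjusted p = 0.00521) and Ch25h by 3.04 (SE 0.43, adjusted p = 0.00855). Socs1, an inhibitor of JAK kinases, was at 843 ± 13.2 in KO and 146 ± 48.6 in WT cells (SD, n = 3 each; 2.58, SE 0.46, adjusted p = 0.0336). In all 31 probe sets were higher in KO and 5 lower. The lower ones were Srsf10 (-2.40, adjusted p = 0.0347; its second probe set at 0.47), C030006K11Rik (-2.31, adjusted p = 0.0164), the fatty acid oxidation gene Cpt1a (-1.58, adjusted p = 0.0343), Igf1 (-1.47, adjusted p = 0.0336; its second probe set at 0.04) and the same unnamed probe set as at 100 min (-4.09, SE 0.33, adjusted p = 8.58e-05). Socs3 was at -3.85 (first probe set, adjusted p = 0.102) and -2.65 (second probe set, adjusted p = 0.252) and was not called; within replicates 1 and 2 it was called at -5.15 (SE 0.39, adjusted p = 0.00109) and -3.63 (SE 0.54, adjusted p = 0.0189).

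Other interferon-inducible genes were higher too, Gbp3 by 3.31 (SE 0.46), Ifi47 by 3.11 (SE 0.57), Casp4 by 2.70 (SE 0.53) and Irf1 by 2.15 (SE 0.36). The Casp4 difference was there before IL-6, although not called. Its unstimulated means were 342.5 in KO and 52.0 in WT cells, with 1 of the WT arrays at the floor. Of the NF-kappaB list 4 of 38 were higher, Ccl7, Ccl2 (4.60), Ccl12 (3.97) and Ccl4 (1.98), and 6 adjusted over the list alone (median 0.27, adjusted p = 2.54e-05, and adjusted p = 0.00642 with an estimated correlation). Of the STAT3 list 1 of 40 was higher, Timp1, an inhibitor of metalloproteinases (1.84, adjusted p = 0.045); adjusted over the list alone 8 were higher and 1 lower (median 0.36, adjusted p = 0.000187, and adjusted p = 0.00943 with an estimated correlation). Of the type I interferon list 2 of 38 were higher, Cxcl10 (2.34) and Plscr1 (1.83), and 10 adjusted over the list alone (median 0.92, adjusted p = 2.29e-12; adjusted p = 0.147 with an estimated correlation). Of the MHC class I list 1 of 16 was higher, Tap1 (1.57, SE 0.22), and 2 adjusted over the list alone (median 0.25, adjusted p = 0.00315; adjusted p = 0.178 with an estimated correlation). Of the alternative activation list 0 of 15 were higher and 1 lower, Igf1; adjusted over the list alone 2 were higher and 1 lower (median 0.71, adjusted p = 0.0237; adjusted p = 0.0969 with an estimated correlation). Of the JAK-STAT and gp130 parts 1 of 35 was higher, Socs1, and the list was not called (adjusted p = 0.112). Xist and Eif2s3y also separated the WT from the KO arrays in this comparison, on all 6 arrays.

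All 36 calls at 400 min had the same direction within replicate 3 and within replicates 1 and 2. These arrays had made the calls, so the agreement is not separate support. A fit of only the groups compared called fewer than the 36, as counted further below. With replicate 3 as a batch block 85 were called and within replicates 1 and 2 134. Without the array labelled KO 400 min replicate 3 57 were called (35 higher and 22 lower), of which 28 were among the 36. The count was 17 and 15 without KO 400 min replicate 1 and 2, 11 and 14 without WT 400 min replicate 2 and 3, 21 without KO unstimulated replicate 2 and 56 without WT 100 min replicate 3. Iigp1, Gbp2, Gbp3, Ch25h and Tap1 kept their calls with each of the 17 arrays left out. The other named genes each lost theirs without 1 or more of the WT 400 min and KO 400 min arrays, and Ccl2, Ifi47, Casp4, Socs1, Cxcl10, Timp1, Plscr1, Igf1, Cpt1a and Srsf10 also without arrays of other groups; each array except WT 100 min replicate 3 removed the call of 1 or more of these genes when left out. Socs1, Cxcl10, Timp1, Igf1 and Srsf10 lost theirs without the array labelled KO 400 min replicate 3. Highest adjusted p-values were 0.0926 for Ccl7, 0.185 for Ccl2, 0.124 for Ccl12, 0.141 for Ifi47, 0.199 for Casp4, 0.117 for Socs1, 0.147 for Cxcl10, 0.0957 for Irf1, 0.0619 for Ccl4, 0.183 for Timp1, 0.167 for Plscr1, 0.124 for Selp and for Igf1, 0.129 for Cpt1a, 0.0794 for C030006K11Rik and 0.16 for Srsf10. The alternative activation list lost its call without WT 400 min replicate 1 or KO 400 min replicate 1 or 2 (highest adjusted p = 0.153).

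Whether the response itself differed between the genotypes was tested as the KO change minus the WT change. For single genes it was not shown to differ: limma called 0 probe sets at 100 min (smallest adjusted p = 0.0863) and 0 at 400 min (smallest adjusted p = 0.1), and 361 and 531 had an unadjusted p under 0.05. By chance 494 would, so the count at 100 min lay under that number and the count at 400 min near it. Named values at 400 min included Ccl7 (5.47, SE 1.57, adjusted p = 0.518), Arg1 (4.33, SE 1.25, adjusted p = 0.518), Gbp3 (3.67, SE 0.68, adjusted p = 0.181), Gbp2 (3.60, SE 0.66, adjusted p = 0.181), Irf1 (2.65, SE 0.53, adjusted p = 0.217) and Tap1 (1.79, SE 0.33, adjusted p = 0.181). At 100 min they included Jun (2.91, SE 0.62), Irf1 (2.28, SE 0.53) and Ccl4 (2.19, SE 0.48), each with an adjusted p of 0.787.

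For gene groups the difference was called. At 400 min the STAT3 list differed by 0.47, with 0 of 40 called and 1 adjusted over the list alone (adjusted p = 0.00286, and adjusted p = 0.0206 with an estimated correlation), and the NF-kappaB list by 0.28, with 0 of 38 called and 3 adjusted over the list alone (adjusted p = 0.0107, and adjusted p = 0.0449 with an estimated correlation). The type I interferon list differed by 1.19, with 0 of 38 called and 4 adjusted over the list alone (adjusted p = 3.49e-12; adjusted p = 0.147 with an estimated correlation), and the MHC class I list by 0.18, with 0 of 16 called and 2 adjusted over the list alone (adjusted p = 0.022; adjusted p = 0.287 with an estimated correlation). Cell cycle genes differed by -0.58, with 0 of 45 called and 0 adjusted over the list alone (adjusted p = 0.000148; adjusted p = 0.722 with an estimated correlation). At 100 min the STAT3 list differed by 0.45, with 0 called and 0 adjusted over the list alone (adjusted p = 0.00765, and adjusted p = 0.0353 with an estimated correlation). Then the type I interferon list differed by 0.83, with 0 adjusted over the list alone (adjusted p = 4.18e-06; adjusted p = 0.359 with an estimated correlation), and the cell cycle list by -0.35, with 0 adjusted over the list alone (adjusted p = 0.0247; adjusted p = 0.797 with an estimated correlation). Within replicates 1 and 2 the list of STAT3, IL-6 and IL-10 targets differed by 0.43 at 400 min (adjusted p = 0.00193) and with replicate 3 as a batch block by 0.35 (adjusted p = 0.00136). The cell cycle list, higher on replicate 3 arrays, differed by -0.08 at 100 min with that block (adjusted p = 0.603) and by -0.35 at 400 min (adjusted p = 0.00223).

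**Figure D2:**
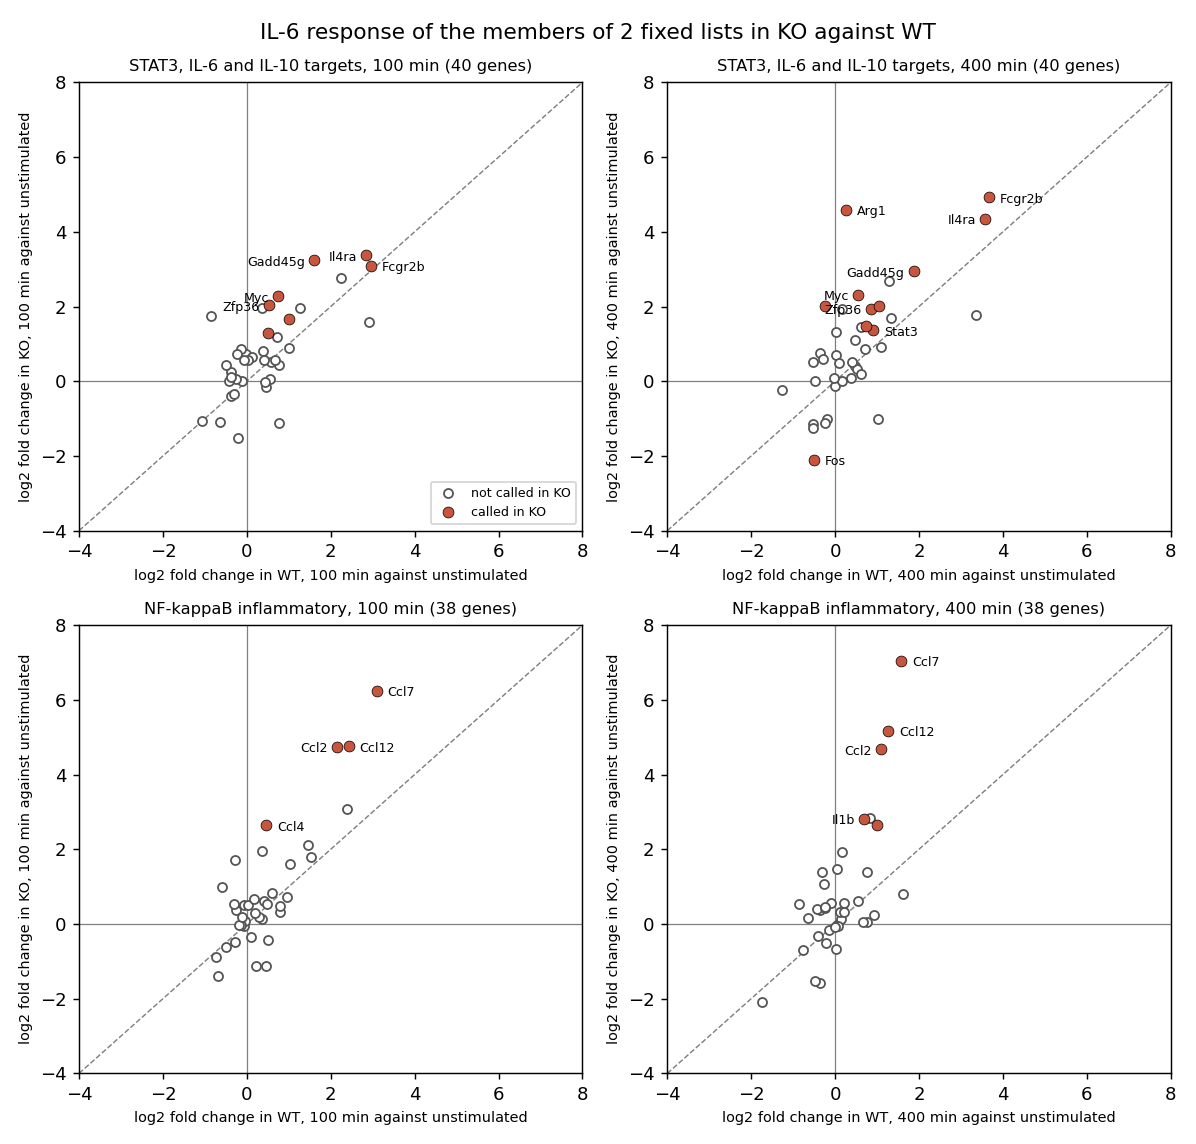
Log2 fold change of each gene in WT (horizontal) and KO macrophages (vertical) against unstimulated cells, for the 40 tested genes of the STAT3 list and the 38 of the NF-kappaB list, at 100 and 400 min; filled points were called in KO cells and the dashed line marks equal responses. At 400 min the KO minus WT difference had a median of 0.47 for the STAT3 list and 0.28 for the NF-kappaB list.

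The single-gene count of the difference at 400 min moved with replicate 3 set as a batch block or left out, and with the limma settings used. At 400 min 5 probe sets were called with that block and 17 within replicates 1 and 2, all 17 higher in KO, among them Arg1 (5.99, SE 0.69, adjusted p = 0.0235), Ccl7 (4.47, SE 0.46, adjusted p = 0.0138) and Gbp2 (3.23, SE 0.30, adjusted p = 0.0112). The Arg1 value rests on replicates 1 and 2: within replicate 3 Arg1 differed by 0.04 between KO and WT cells at 400 min. Other limma settings called 8 with a trended and robust fit and 7 with array weights at 400 min, and 0 with each at 100 min. At 100 min 0 were called with the block and 0 within replicates 1 and 2. The count at 100 min was 3 without WT unstimulated replicate 1 and 1 without KO unstimulated replicate 2 or KO 400 min replicate 2. At 400 min it was 8 without WT 100 min replicate 3 and 1 without WT unstimulated replicate 1, KO 400 min replicate 2 or the array labelled KO 400 min replicate 3. At 400 min the MHC class I list lost its call without WT unstimulated replicate 1, KO unstimulated replicate 2, KO 400 min replicate 2, WT 400 min replicate 3 or the array labelled KO 400 min replicate 3 (highest adjusted p = 0.116), the NF-kappaB list without WT unstimulated replicate 1 (adjusted p = 0.0729) and the cell cycle list without KO unstimulated replicate 3 (adjusted p = 0.142). At 100 min the cell cycle list lost it without either WT unstimulated array, KO 100 min replicate 1 or 2, WT 100 min replicate 3 or KO unstimulated replicate 3 (highest adjusted p = 1).

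Genes called in KO cells mostly moved the same way in WT cells. Of the 53 probe sets that rose in KO at 100 min, 51 had a positive value in WT, with medians of 2.28 in KO and 1.09 in WT. Of the 118 that rose at 400 min, 95 were positive in WT, with medians of 1.96 and 0.73. Of the 4 that fell at 100 min 3 were negative in WT (medians -1.82 and -0.40), and of the 62 that fell at 400 min 56 were (medians -1.52 and -0.50). These probe sets were chosen for their change in KO cells, which enlarges the KO medians. Across all tested probe sets, which are not independent replicates, the WT and KO changes correlated with Pearson's r of 0.178 at 100 min and 0.169 at 400 min (Spearman's rho 0.158 and 0.152).

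Within KO cells 43 probe sets rose at both times and 2 fell at both, where lists drawn independently would share 0.634 and 0.0251. The times share the unstimulated arrays: the KO changes at 100 and 400 min correlated with r = 0.57, against 0.499 in 100 simulations with no effect, and their covariance was 0.242 against 0.141. In WT cells r was 0.61 against 0.599 and the covariance 0.265 against 0.211, and 1 probe set, that of Il4ra, rose at both times, where independent lists would share 0.000101. The unstimulated arrays are too few to be divided between the times, so part of the excess may come from them.

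The remaining lists were not called in any of the 9 comparisons. The lowest adjusted p was 0.422 for MHC class II genes (12 tested), 0.289 for acute phase and complement genes (18), 0.0834 for immediate early genes (28), 0.209 for lysosome and phagocytosis genes (27) and 0.781 for macrophage markers (22). Among other cells it was 0.422 for neutrophil and myeloid precursor markers (14 tested), 0.294 for B cell markers (14), 0.195 for T and NK cell markers (11), 0.522 for erythroid and megakaryocyte markers (11) and 0.253 for dendritic cell and osteoclast markers (9). For the 28 chromosome 11 neighbours of Socs3 it was 0.08.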

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

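The tests of the pattern in the STAT3 list, of the Socs3 signal and of the RNA of replicate 3 below were chosen after the result was seen; the regroupings of the arrays and the test of other cell types on replicate 3 were planned before it.

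The difference between the KO and WT responses was itself tested and was called for these lists. At 100 min the median difference was 0.83 for the type I interferon list, 0.453 for the STAT3 list and -0.351 for the cell cycle list. At 400 min it was 1.188 for the type I interferon list, 0.176 for MHC class I genes, 0.473 for the STAT3 list, 0.275 for the NF-kappaB list and -0.577 for the cell cycle list. With an estimated correlation the calls of the STAT3 list at both times and of the NF-kappaB list at 400 min held.

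The list of STAT3, IL-6 and IL-10 targets responded more in KO cells at 400 min. The replicate 3 arrays are argued against as the whole cause, since within replicates 1 and 2 the median difference was 0.434 and still called. The scaling between arrays stays open: with the values as deposited the difference was 0.474, but that setting moved almost nothing, so it decides nothing. The sex of the cells stays open: the lowest Eif2s3y value of the WT arrays was 2.19 times the highest of the KO arrays, so sex and genotype cannot be told apart on these arrays. The loss of SOCS3, the difference the design names, may also account for it and was not separated from the sex of the cells.

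Socs3 on the array labelled KO 400 min replicate 3 stood at 903 (first probe set, normalized), where the other 8 KO arrays lay between 16.5 and 179. A fault of 1 probe set is argued against, since the other Socs3 probe set read 793 there and at most 333 on the other KO arrays. Cells of this study's WT samples are argued against too: the unnamed probe set that is low in KO cells would then be near 198 and Eif2s3y near 259, and they read 5.54 and 81.9. Both may follow the sex of the cells, so they may not be separate evidence. Cells with Socs3 but without the Y-linked signal, such as recipient cells, may have been present: over 16 probe sets that separate the genotypes on the other arrays, sex-linked ones and that unnamed probe set left out, the median position of this array between KO and WT was 46.8%, and those of the other KO arrays, each over the 10 to 15 probe sets found in the same way without it, lay between -32.7% and 32%. The margin over the highest of these is small, the probe sets left out were chosen after their values were seen, and no biological explanation was tested. The 16 probe sets were also scattered, so the median does not show that each lay between the genotypes. On this array Gsr read 645, within the WT range (606 to 1040), and Apoe 524, within the KO range (29.9 to 2080). Others, such as Ctla2b at 651, lay between the ranges.

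The 5 arrays of replicate 3 differed from the other 12 in 717 probe sets (364 higher and 353 lower). More degraded RNA is argued against: the mean 3'/5' ratio of Actb was 1.4 on these arrays and 1.94 on the others (exact permutation test, two-sided, p = 0.0103), and that of Gapdh 0.85 and 1.49 (exact permutation test, two-sided, p = 0.036). Other cell types stay open: 0 lists of other cells were called higher on these arrays, but the lists are short and none but the neutrophil and myeloid precursor list, lower at a median of -0.5 (adjusted p = 0.00548; adjusted p = 0.0983 with an estimated correlation), was called. The medians that were not called were 0.23 for dendritic cells and osteoclasts (adjusted p = 0.39), 0.24 for mast cells (adjusted p = 0.869, tested direction lower), 0.08 for T and NK cells, -0.1 for erythroid cells, -0.11 for B cells and -0.19 for fibroblasts; the macrophage list was lower, at -0.26 (adjusted p = 0.0411; adjusted p = 0.177 with an estimated correlation). A batch of culture, labelling or hybridisation may be the cause and stays open, since the labels give no dates, and no biological explanation was tested; the cell cycle list was higher on these arrays by a median of 0.75.

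Splitting the same 6 arrays of a comparison into groups of 3 in every other way gives 10 splits, the real one included, which are too few for a share under 0.05. For KO 100 min against unstimulated the real split called 57 probe sets and the highest other 3. For KO 400 min against unstimulated these numbers were 180 and 1, for KO against WT at 100 min 4 and 1, and for KO against WT at 400 min 36 and 2. In each comparison 1 split, the real one, called as many. In the first and the last, a split that called the highest other number kept both replicate 3 arrays together; within replicates 1 and 2 those comparisons called 125 and 134.

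Outside the genes tested, the array control probe set AFFX-MurIL4_at differed between groups: by 1.96 in WT cells at 400 min against unstimulated (adjusted p = 0.0436), by -1.96 in KO against WT at 400 min (adjusted p = 0.0172) and by -3.52 in the difference between the responses at 400 min (adjusted p = 0.00336). Its means before the floor of 22.01 was set were 11.9, 28.6 and 85.9 in WT cells unstimulated and at 100 and 400 min, and 68.0, 71.9 and 14.9 in KO cells. All arrays of unstimulated WT cells (5.24 to 18.6) and of KO cells at 400 min (7.1 to 19.4) lay under the floor, so each of these differences is at least as large as given. The probe set was dim throughout, with a highest value of 103 on a KO 100 min array. The 66 control probe sets were fitted with limma apart from the genes and adjusted over those 66. Their adjusted p-values therefore cannot be set beside those of the genes. Single arrays that lie far from their group were not tested, since the groups hold 2 or 3 arrays.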

How the results depend on the processing

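The alternatives with replicate 3 as a batch block, within replicates 1 and 2, and with a floor at the 40th percentile were chosen after seeing the data; the others were planned. Counts are of called probe sets, given in the order of the comparisons. For WT at 100 min (1 as reported) they were 2 without a filter, 4 with a stricter filter, 2 with the values as deposited, 5 with the replicate block, 0 with only the groups compared, 5 with a trended and robust fit, 5 with array weights, 3 with the batch block and 22 within replicates 1 and 2. For WT at 400 min (1) they were 2 without a filter, 3 with a stricter one, 3 with the replicate block, 0 with only the groups compared, 8 trended and robust, 4 with weights, 3 with the batch block, 16 within replicates 1 and 2 and 5 with the higher floor. For KO at 100 min (57) they were 86 with the replicate block, 0 with only the groups compared, 86 trended and robust, 94 with weights, 94 with the batch block and 125 within replicates 1 and 2. For KO at 400 min (180) they were 305, 52, 290, 483, 332 and 309 in that order, and 283 with the higher floor. For unstimulated KO against WT (0) they were 1 without a filter, 1 with a stricter one, 1 as deposited and 9 within replicates 1 and 2. For KO against WT at 100 min (4) they were 7 with a stricter filter, 2 as deposited, 10 with the replicate block, 0 with only the groups compared, 14 trended and robust, 23 with weights, 16 with the batch block, 40 within replicates 1 and 2 and 10 with the higher floor. For KO against WT at 400 min (36) they were 57 with the replicate block, 2 with only the groups compared, 73 trended and robust, 132 with weights, 85 with the batch block, 134 within replicates 1 and 2 and 68 with the higher floor. For the difference at 400 min (0) they were 3 without a filter, 4 with the replicate block, 5 with only the groups compared, 8 trended and robust, 7 with weights, 5 with the batch block, 17 within replicates 1 and 2 and 3 with the higher floor; the difference at 100 min stayed at 0 in each of these fits. The correlation of WT and KO changes at 100 min (0.178) was 0.14 without a filter, 0.269 with a stricter one, 0.208 with the replicate block and with the batch block, and 0.341 with the higher floor. At 400 min (0.169) it was 0.132, 0.251, 0.208, 0.208 and 0.3, and 0.21 within replicates 1 and 2. For all of these changes the cause was not tested.

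With each array left out in turn the counts ranged from 0 to 20 and from 0 to 16 (WT at 100 and 400 min), from 24 to 79 and from 73 to 231 (KO), from 0 to 17, from 1 to 12 and from 11 to 57 (KO against WT unstimulated, at 100 and at 400 min), and from 0 to 3 and from 0 to 8 (differences). The correlations ranged from 0.121 to 0.222 and from 0.102 to 0.21. The count for KO at 400 min was 231 without WT 100 min replicate 3. Leaving out an array of unstimulated WT cells leaves that group 1 array, which is assumed to vary like the other groups. Of the 91 named gene calls 33 and of the 43 list calls 29 were kept with each of the 17 arrays left out, and none reversed.

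Named gene calls kept under other settings were 87 of 91 with a floor at the 2nd percentile, 77 without a filter, 81 with a stricter one (10 were then not tested), 86 as deposited, 90 with the replicate block, 91 with the batch block, 77 within replicates 1 and 2 and 76 with the higher floor, which left Foxd1 in KO cells at 100 min and Plpp1 in KO cells at 400 min with a fold change of 0. List calls kept were 42 of 43 with the floor at the 2nd percentile, 41 without a filter, 40 with a stricter one, 43 as deposited, 38 with the replicate block, 38 with the batch block, 37 within replicates 1 and 2, 40 with the higher floor, 38 with the mean over probe sets and 17 with an estimated correlation. None of these calls reversed.

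Arrays with the same replicate number did not pair by the rule set in advance: deviations from the group means correlated over 0.1 for 1 of 15 pairs of number 1, 0 of 15 of number 2 and 10 of 10 of number 3, while 14 of 17 arrays correlated best with their own number, a hint from the data. The replicate block moved the counts as given above. The scaling moved the median fold change of no comparison by more than 0.1. Signal over background limits the dim genes: between 216 and 321 of the 9871 tested probe sets lay at the floor on each array, and detection calls were not used here. For Cd247, Myc and other genes at the floor in a group, the fold change between a pair of groups is a lower bound. A difference between the KO and WT responses is not bounded in that way.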

Other observations

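The tests below were all chosen after the data were seen, and none was planned.

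The type I interferon list lay lower at 400 than at 100 min of IL-6 in macrophages of both genotypes within replicates 1 and 2. There limma called in WT cells 3 probe sets higher and 14 lower, among them the guanylate-binding protein genes Gbp7 (-3.10, SE 0.20, adjusted p = 0.00126) and Gbp3 (-2.84) and the interferon-induced genes Ifit2 (-2.41), Ifit3 (-2.34) and Ifit1 (-2.21). Over all arrays 0 were called, and 622 had an unadjusted p under 0.05. In WT cells the type I interferon list had a median of -0.82 within replicates 1 and 2 (adjusted p = 4.65e-16, and adjusted p = 0.00496 with an estimated correlation) and of -0.63 over all arrays (adjusted p = 6.21e-09; adjusted p = 0.314 with an estimated correlation). In KO cells the median of that list was -0.20 within replicates 1 and 2 (adjusted p = 2.23e-05, and adjusted p = 0.0278 with an estimated correlation) and -0.14 over all arrays (adjusted p = 0.259). The change of the type I interferon list from 100 to 400 min differed between KO and WT by 0.54 over all arrays (adjusted p = 0.00191; adjusted p = 0.525 with an estimated correlation) and by 0.28 within replicates 1 and 2 (adjusted p = 0.02; adjusted p = 0.17 with an estimated correlation).

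In KO macrophages some genes rose between the times and others fell. Within replicates 1 and 2, Arg1 was 3.88 (SE 0.49, adjusted p = 0.0402) and Fgl2 2.34 (SE 0.23, adjusted p = 0.027) higher at 400 than at 100 min, and Pdcd4 (-4.06), Ifit3 (-3.06) and the cell cycle genes E2f1 (-2.20) and Rrm2 (-1.79) were lower; 5 were called higher and 13 lower. Over all arrays 0 were called, and 891 had an unadjusted p under 0.05. The cell cycle list was at -0.42 within replicates 1 and 2 (adjusted p = 4.27e-06, and adjusted p = 0.0278 with an estimated correlation) and at -0.58 over all arrays (adjusted p = 1.6e-06; adjusted p = 0.525 with an estimated correlation). In the difference between KO and WT over all arrays, Cd247 (-4.43, SE 0.56) and Rabgap1l (-4.06, SE 0.50) were called, each with an adjusted p of 0.00929. Neither call held within replicates 1 and 2, where 1 probe set was called higher and 0 lower. Cd247 lay at the floor on all 3 arrays of WT 100 min.

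Without the replicate 3 arrays 22 probe sets were called in WT cells at 100 min of IL-6 and 16 at 400 min. At 100 min Socs3 rose by 4.76 (SE 0.39, adjusted p = 0.00341), with Ccl7 (3.88), Ccl2 (3.43), Gbp7 (3.07) and Gbp2 (2.43); at 400 min Socs3 rose by 4.80 (SE 0.39, adjusted p = 0.0075), with Fcgr2b (3.09) and Fgl2 (2.55), while Ifit3 fell by 1.79 (SE 0.21, adjusted p = 0.0299). Unstimulated KO cells then differed from WT cells in 9 probe sets, among them Hpgd, which encodes a prostaglandin-degrading dehydrogenase (-6.06, SE 0.63, adjusted p = 0.03), Gdf3 (-3.22, SE 0.33, adjusted p = 0.03) and the macrophage elastase gene Mmp12 (1.96, SE 0.24, adjusted p = 0.0379). Each group of these comparisons has 2 arrays. These genes were named after their values were seen.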
